A study of Mus musculus with 12 samples.

How the data were processed

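Total RNA of whole kidneys from adult male C57BL/6 mice was measured on 12 arrays of a mouse whole-genome BeadChip, 3 after sham surgery and 3 each at 6 h, 48 h and 7 d after 25 min of ischemia. The labels call the kidneys of a group biological replicates. The deposited table held 1 intensity per probe and array for 45281 probes, which the authors processed with GenomeStudio, per the submitters' processing notes. Its version, the normalization and any background step are not given in the sources used here. From the values, the deposited intensities were on a linear scale and shared 1 distribution, with a 75th percentile of 208, a lowest value of 57.79 and a highest of 60084 on each array and medians of 94.2 to 94.4. They were therefore treated as quantile normalized and not background-subtracted. Quantile normalization removes differences in overall brightness between arrays, so a change shared by most transcripts would not show, and the unsubtracted background makes changes of dim probes look smaller. No detection p-value was used here.

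Intensities were taken as log2(value + 16) with no further normalization, so that changes of dim genes are understated. Gene names came from the platform annotation. Of the probes, 34885 had 1 gene symbol, 18 had several and 10378 had none there. Entrez identifiers of 34807 of the 1-symbol probes were matched to a RefSeq gene table of mouse, which changed 0 symbols. Probes were kept if they lay above the median of their array on at least 3 of 12 arrays, which left 22211 of the 1-symbol probes, and the brightest probe stood for each gene, giving 13630 genes. For 5563 genes more than 1 probe passed. Of 2718 other probes of genes called at 6 h against sham, 1106 were called the same way, 19 the opposite way and 1593 were not called. These numbers were 572, 18 and 1189 of 1779 at 48 h, 593, 48 and 1313 of 1954 at 7 d, 977, 21 and 1497 of 2495 for 48 h against 6 h, and 160, 0 and 436 of 596 for 7 d against 48 h. Arrays of 1 group correlated at r of 0.981 or more over all probes, and at most 0.0663% of probes had identical values on any pair of arrays, so no array was a copy of another.

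Groups were compared with limma 3.58.1 in R 4.3.3, with input read by the data.table package, version 1.17.8. One linear model with a mean per group was fitted to all 12 arrays, with empirical Bayes moderation, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Each time was compared with sham, and 48 h with 6 h and 7 d with 48 h, and a moderated F test asked for any difference among the 4 groups. Log2 changes are given with their standard error. The groups, the model, the gene lists, the settings to be varied and the rule for named genes were fixed before the data were examined, except for the normexp background correction, the fit without the third kidneys at 48 h and 7 d and the male-biased gene list, which were added afterwards. The rule named, in each comparison, the 8 largest increases and the 8 largest decreases among called genes whose groups did not overlap, up to 4 members of each list by smallest adjusted p, and Havcr1, Lcn2, Nfkbia, Tnfaip3, Ccl2, Cxcl1, Slc34a1 and Umod. Across all genes the groups did not overlap in 40.2% at 6 h, 34.2% at 48 h and 38.1% at 7 d against sham, 42.8% for 48 h against 6 h and 25.3% for 7 d against 48 h, where chance gives 10%.

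The 31 gene lists covered tubular injury, NF-κB pathway and target genes, immediate early genes, heat shock proteins, the unfolded protein response, hypoxia and glycolysis, oxidative stress, acute phase and complement, interferon response, cell cycle, p53 targets, extracellular matrix, regeneration, cell death, fatty acid oxidation, the respiratory chain, the nephron segments, podocytes, endothelium, macrophages, neutrophils, T and NK cells, B and plasma cells, dendritic cells and MHC class II, erythroid cells, perirenal fat, adrenal gland and common reference genes. Of 558 list entries, 506 had a named probe and 457 were tested. The injury list shares Cdkn1a, Sox9 and Vcam1 with other lists. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, all in limma, with adjustment over 155 tests.

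The model was tested on simulated data in which 200 of 13630 genes changed. Of genes changed by 0.5, 1 and 2 on the log2 scale, 46.27%, 92.54% and 100% were recovered for 6 h against sham, 44.78%, 95.52% and 100% for 48 h against sham, and 40.3%, 94.03% and 100% for 7 d against sham. For 48 h against 6 h these shares were 41.79%, 86.57% and 100%, and for 7 d against 48 h 59.7%, 92.54% and 98.48%. False calls were 3.636%, 4.192%, 5.455%, 7.879% and 5.65% of the calls in the same order of comparisons. The simulated noise was independent between genes and arrays, with 1 variance per gene for all groups and no BeadChip difference. These shares therefore test the model under its own assumptions and may not hold for the real arrays.

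The settings varied were the normalization, the offset, the intensity filter, the rule for probes of 1 gene, the variance model, array weights, the arrays in the fit, the replicate number as a block, the thresholds, the correlation in the list tests and leaving out each kidney in turn. Probes with no gene symbol were left out of the gene counts and are reported apart. Genome coordinates were not used here.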

Results

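Gene expression was measured in whole kidneys of adult male C57BL/6 mice after sham surgery and at 6 h, 48 h and 7 d after ischemia-reperfusion injury. The vessels of the remaining left kidney were clamped for 25 min and then released. Sham animals had the same operation with no clamp. How long after surgery their kidneys were taken is not given, so time since surgery cannot be told apart from ischemia here. The series' design text calls the controls healthy, whereas the sample labels name sham surgery. Each of the 4 groups held 3 biological replicates, with 1 array per kidney on a mouse whole-genome BeadChip, a slide of bead arrays read as fluorescence. The study's title places the work in the context of NF-κB activity in tubular epithelium, and the comparisons below ask how the kidney transcriptome changed over time after ischemia. The number of arrays, 3 per group, limits the precision of every comparison. Sham and 6 h arrays shared 1 BeadChip and 48 h and 7 d arrays the other. The comparisons of 6 h with sham and of 7 d with 48 h therefore lay within a BeadChip, and in the other 3 comparisons BeadChip and group cannot be told apart.

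Of 13630 genes tested, 6079 (44.6%) differed among the 4 groups, any BeadChip difference included (limma F test, adjusted p under 0.05). The first principal component, with 36.8% of the variance, placed the 6 h kidneys apart from all others. The second, with 32.9%, placed sham kidneys at one end and the injured kidneys at lower scores. Along this second component kidneys spread widely, from 2.79 to -32.1 at 48 h and from 7.84 to -28.1 at 7 d.

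**Figure D1:**
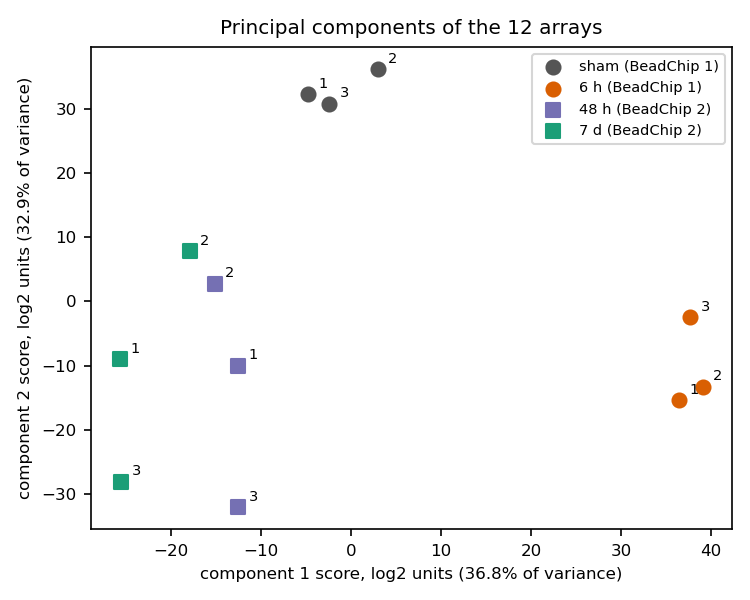
Scores of the 12 arrays on the first 2 principal components of log2 expression over 13630 genes, with 1 point per kidney, colours for groups, shapes for the 2 BeadChips and replicate numbers beside the points. The 6 h kidneys lie between 36.5 and 39.1 on component 1, and all other kidneys at 3 or below.

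At 6 h, kidneys showed a strong injury and stress response compared with sham. The largest increases were in Cxcl1, a neutrophil-attracting chemokine, with a log2 change of 6.11 ± 0.38 (SE, 3 against 3 kidneys), and in Lcn2, the iron-siderophore binding protein used as a urinary injury marker, with 5.77 ± 0.72. Krt20, an epithelial keratin, rose by 5.68 ± 0.41, Chac1, a glutathione-degrading enzyme of the stress response, by 5.22 ± 0.25 and Havcr1, which encodes kidney injury molecule 1, by 4.75 ± 0.51. The cell-cycle inhibitor Cdkn1a (4.52 ± 0.47), the TWEAK receptor Tnfrsf12a (4.49 ± 0.40) and the transcription factor Sox9 (4.38 ± 0.45) followed. The adjusted p of these 8 genes was 0.00025 or less. The mean Havcr1 intensity was 128.6 ± 27.2 in sham (SD, n = 3) and 3901 ± 964 at 6 h, and that of Lcn2 was 203.8 ± 84.2 and 11700 ± 2790. Other probes of Cdkn1a gave 2.88 and 2.98, and another probe of Sox9 gave 1.90.

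Of 18 measured tubular injury markers, 14 rose at 6 h and none fell (14 adjusted over the list alone), with a median log2 change of 2.40 (camera, adjusted p = 6.8e-12, and adjusted p = 0.456 with an estimated correlation between genes). Plaur, the urokinase receptor, rose by 2.15 ± 0.18 and Lgals3, which encodes galectin 3, by 2.82 ± 0.26. All 21 measured immediate early and stress transcription factors rose (21 adjusted over the list alone), with a median of 1.96 (adjusted p = 1.78e-20, and adjusted p = 0.271 with an estimated correlation). Among them were Atf3 (3.29 ± 0.21), the phosphatase gene Dusp5 (3.11 ± 0.21), Fosb (1.65 ± 0.10) and Maff (1.37 ± 0.10). Of 15 genes of the unfolded protein and integrated stress response, 11 rose (11 adjusted over the list alone), with a median of 0.92 (adjusted p = 5.76e-09, and adjusted p = 0.271 with an estimated correlation). Besides Chac1, these included Trib3 (3.67 ± 0.24), Ppp1r15a (2.34 ± 0.13) and Dnajb9 (1.48 ± 0.08). Heat shock proteins and chaperones rose in 9 of 14 (9 adjusted over the list alone), with a median of 0.84 (adjusted p = 1.23e-06, and adjusted p = 0.271 with an estimated correlation). Hspa1a (2.95 ± 0.32) and Hspa1b (2.06 ± 0.14) led the list and are near-identical genes that the probes may not separate. Oxidative stress response genes rose in 7 of 14 (8 adjusted over the list alone), with a median of 0.76 (adjusted p = 1.65e-05, and adjusted p = 0.456 with an estimated correlation). Hmox1, the heme-degrading enzyme, rose by 4.20 ± 0.28, Srxn1 by 3.64 ± 0.35 and the metallothionein Mt1 by 1.62 ± 0.18. Of 14 p53 targets and DNA damage genes, 7 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.44 (adjusted p = 0.00211, and adjusted p = 0.44 with an estimated correlation), among them Gadd45a (2.33 ± 0.29) and Mdm2 (0.79 ± 0.10).

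Genes of the NF-κB pathway and its targets rose at 6 h in 21 of 34 measured members and fell in none (25 adjusted over the list alone), with a median log2 change of 0.77 (camera, adjusted p = 5.2e-14, and adjusted p = 0.271 with an estimated correlation). Besides Cxcl1, the list's smallest adjusted p values were those of Tnfaip3, which encodes the feedback inhibitor A20 (1.32 ± 0.09), Il6 (1.20 ± 0.08) and Cxcl2 (3.34 ± 0.24). The inhibitor gene Nfkbia rose by 1.83 ± 0.17 (adjusted p = 3.53e-05). Ccl2, the monocyte-attracting chemokine, rose by 0.76 ± 0.19 (adjusted p = 0.0126). Acute phase and complement genes rose in 9 of 16 (9 adjusted over the list alone), with a median of 0.70 (adjusted p = 0.000177, and adjusted p = 0.456 with an estimated correlation), including Socs3 (3.75 ± 0.45) and Stat3 (1.90 ± 0.17). Markers of neutrophils rose in 5 of 13 (5 adjusted over the list alone), with a median of 0.20 (adjusted p = 0.007, and adjusted p = 0.488 with an estimated correlation). Without the first 6 h kidney this median was 0.114. S100a8 rose by 3.05 ± 0.36, S100a9 by 2.57 ± 0.24 and Retnlg by 1.11 ± 0.14. Of 18 macrophage and monocyte markers, Cd14 alone rose (2.08 ± 0.25, and 1 adjusted over the list alone), and the list's median was 0.031 (adjusted p = 0.611).

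Some genes of the proximal tubule and the collecting duct were lower at 6 h. The largest decrease of all was in Slc4a1, the anion exchanger of acid-secreting collecting duct cells and red blood cells, at -3.31 ± 0.48. Other large decreases were in D630023F18Rik (-2.52 ± 0.28), Igfbp5 (-2.51 ± 0.26), Tmem25 (-2.37 ± 0.23), the succinate receptor Sucnr1 (-2.27 ± 0.20), Bsnd, the chloride channel subunit barttin (-2.15 ± 0.29), Sfrp1 (-2.11 ± 0.29) and Tmem86a (-2.07 ± 0.31), with adjusted p of 0.000763 or less. Proximal tubule genes fell in 8 of 33 (8 adjusted over the list alone), with a median of -0.38 (adjusted p = 0.0124, and adjusted p = 0.779 with an estimated correlation). The lactate transporter Slc5a12 fell by 1.98 ± 0.32 on the log2 scale and the organic anion transporter gene Slc22a8 by 0.76 ± 0.12. Without the first 6 h kidney this list's adjusted p was 0.0664. Collecting duct genes fell in 5 of 14 (5 adjusted over the list alone), with a median of -0.32 (adjusted p = 0.0178, and adjusted p = 0.71 with an estimated correlation), including Hsd11b2 (-1.43 ± 0.23) and the water channel Aqp4 (-1.26 ± 0.22). Without the second sham kidney this list's adjusted p was 0.138. In the thick ascending limb list 3 of 9 genes fell and 1 rose (5 and 1 adjusted over the list alone), with Kcnj1 at -1.74 ± 0.27 and Cldn10 at -1.39 ± 0.21, and in the distal convoluted and connecting tubule list 3 of 9 fell and 1 rose (4 and 1 adjusted over the list alone). Neither list passed the list test, with medians of -0.71 (adjusted p = 0.0676) and -0.41 (adjusted p = 0.362). The thick ascending limb list passed with no intensity filter (adjusted p = 0.039), normexp background correction (0.0447) or the mean of all probes (0.0497), and without the third kidneys at 48 h and 7 d (0.0289). Slc34a1, the main phosphate transporter of the proximal tubule, was not called (-0.19 ± 0.21, adjusted p = 0.575), nor was Umod, which encodes uromodulin (-0.07 ± 0.19, adjusted p = 0.831). The mean Slc34a1 intensity in sham was 51290 ± 1480 (SD, n = 3), close to the highest value of any probe, 60084, so that changes at this brightness may be compressed.

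In all, 1638 genes were higher and 1745 lower at 6 h than in sham (limma, adjusted p under 0.05). Of these, 454 and 228 changed by at least 2-fold. Without the first 6 h kidney 1136 genes were lower, and without the second 1080. A fit of these 2 groups alone, which lie on 1 BeadChip, gave 1663 higher and 1945 lower.

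**Figure D2:**
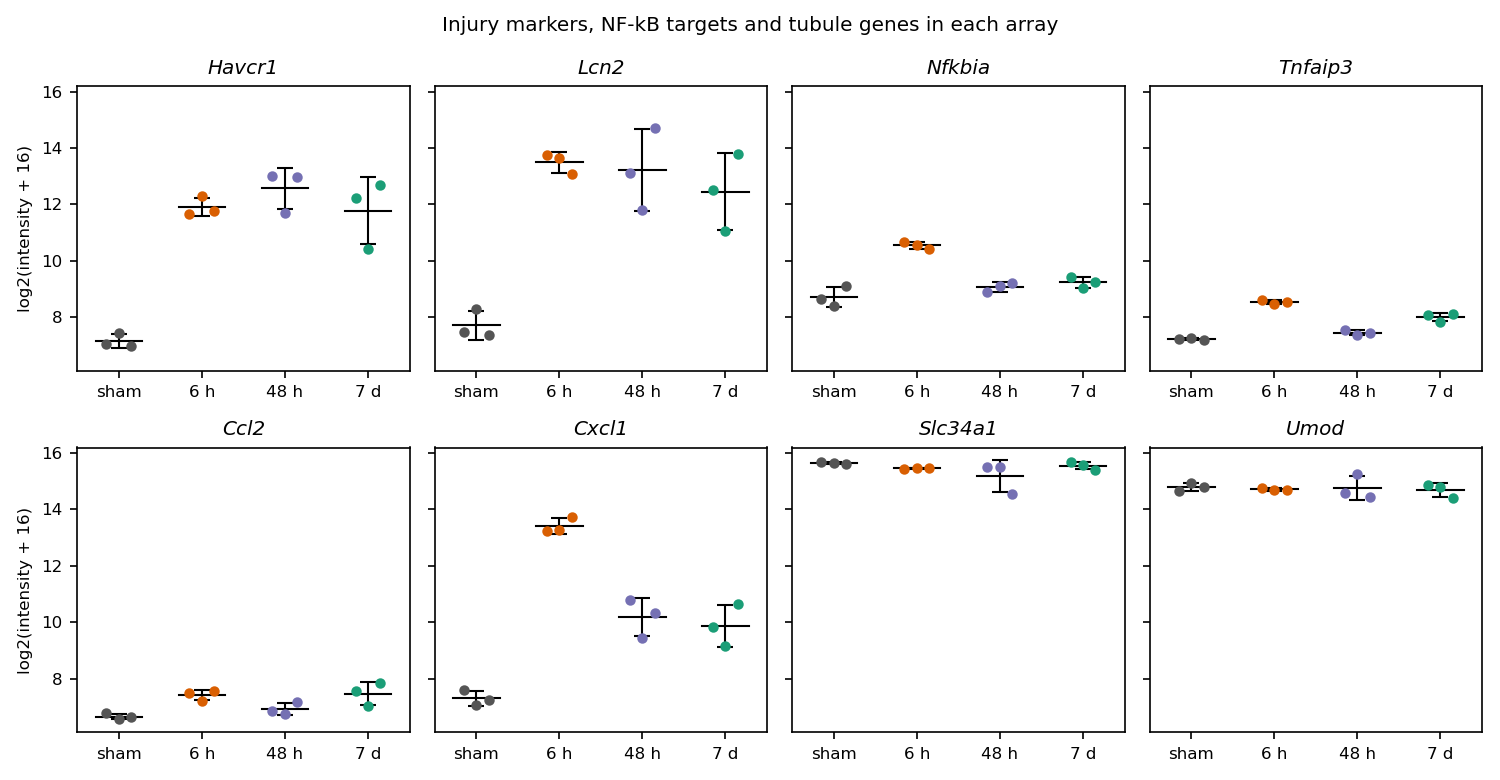
Expression of the 8 genes fixed in advance, as log2(intensity + 16), with 1 point per kidney, horizontal lines for group means and bars for 1 SD (n = 3). Havcr1 and Lcn2 lie above all sham values at each time after injury, Cxcl1 peaks at 6 h, and Slc34a1 and Umod lie near the top of the scale in all groups.

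At 48 h, genes of cell division stood out. All 25 measured cell cycle genes were higher than in sham (25 adjusted over the list alone), with a median log2 change of 2.26 (camera, adjusted p = 3.14e-30, and adjusted p = 0.271 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, was higher by 3.46 ± 0.22, the survivin gene Birc5 by 3.30 ± 0.22, the centromere histone Cenpa by 2.97 ± 0.21 and the mitotic kinase Aurka by 2.42 ± 0.16. Foxm1, a transcription factor of proliferating cells, was higher by 1.54 ± 0.13. Injury markers remained high. Lcn2 was higher by 5.49 ± 0.72 and Havcr1 by 5.41 ± 0.51, followed by the microtubule bundling factor Prc1 (3.80 ± 0.38), the histone gene H2ac22 (3.68 ± 0.30), the metalloproteinase inhibitor Timp1 (3.52 ± 0.53), the actin cross-linker Flnc (3.49 ± 0.39) and S100a6 (3.33 ± 0.29), all with adjusted p of 0.00162 or less. Histone H2A genes share near-identical sequence, so the probe of H2ac22 may read several of them.

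Of 18 tubular injury markers, 16 were higher at 48 h (17 adjusted over the list alone), with a median of 1.93 (adjusted p = 2.09e-12, and adjusted p = 0.456 with an estimated correlation). Genes of the NF-κB list were higher in 11 of 34 (13 adjusted over the list alone), with a median of 0.36 (adjusted p = 7.12e-06, and adjusted p = 0.456 with an estimated correlation). They included Cxcl1 (2.89 ± 0.38), the adhesion molecule Vcam1 (1.74 ± 0.26), Relb (0.86 ± 0.13) and Nfkb2 (0.54 ± 0.10). Nfkbia (0.36 ± 0.17, adjusted p = 0.166), Tnfaip3 (0.23 ± 0.09, adjusted p = 0.104) and Ccl2 (0.27 ± 0.19, adjusted p = 0.369) were not called. Extracellular matrix and myofibroblast genes were higher in 9 of 22 (9 adjusted over the list alone), with a median of 0.67 (adjusted p = 0.000353, and adjusted p = 0.713 with an estimated correlation), among them Col1a1 (1.50 ± 0.24) and Col3a1 (1.50 ± 0.27). Oxidative stress genes were higher in 5 of 14 (7 adjusted over the list alone), with a median of 0.58 (adjusted p = 0.000751, and adjusted p = 0.498 with an estimated correlation), led by the quinone reductase Nqo1 (1.04 ± 0.16). Without the third 48 h kidney this median was 0.335. Acute phase genes were higher in 6 of 16 (7, with 1 lower, adjusted over the list alone), with a median of 0.51 (adjusted p = 0.0067, and adjusted p = 0.507 with an estimated correlation), led by Lrg1 (1.81 ± 0.22). Immediate early genes were higher in 6 of 21 (9 adjusted over the list alone), with a median of 0.44 (adjusted p = 0.00088, and adjusted p = 0.69 with an estimated correlation), including Klf6 (1.72 ± 0.42, not called without the third 48 h kidney, adjusted p = 0.0727, or in a fit of the 2 groups alone, 0.0697). Without the second sham kidney the median of this list was 0.697. The unfolded protein list was higher in 3 of 15 (4, with 1 lower, adjusted over the list alone), with a median of 0.26 (adjusted p = 0.0368, and adjusted p = 0.498 with an estimated correlation). This call was lost without the third 48 h kidney (adjusted p = 0.0554) or the first sham kidney (adjusted p = 0.0752). Of 18 macrophage markers 2 were higher (2 adjusted over the list alone), Cd14 (1.76 ± 0.25) and Chil3 (2.01 ± 0.45), with a median of 0.36 (adjusted p = 0.0144, and adjusted p = 0.779 with an estimated correlation). Without the second sham kidney this list's adjusted p was 0.112, and without the second 48 h kidney 0.056.

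Some genes of the proximal tubule were lower at 48 h. The largest decreases were in Cyp7b1, an oxysterol hydroxylase (-3.94 ± 0.85), Cyp2d9 (-3.65 ± 0.74), the endonuclease Dnase1 (-3.20 ± 0.68), Mettl7a2 (-3.20 ± 0.66), the methyltransferase Inmt (-3.19 ± 0.72), the brush border protease subunit Mep1b (-2.95 ± 0.76), Ugt3a1 (-2.78 ± 0.62) and the organic anion transporter gene Slc22a19 (-2.70 ± 0.64). Their adjusted p was 0.0234 or less, and several belong to families with close relatives that a probe may also read. Proximal tubule genes were lower in 12 of 33 (14, with 1 higher, adjusted over the list alone), with a median of -0.71 (adjusted p = 2.37e-06, and adjusted p = 0.507 with an estimated correlation). Without the third 48 h kidney this median was -0.447. Slc6a19, the neutral amino acid transporter, was lower at -1.73 ± 0.25, the glucose transporter Slc5a2 at -1.55 ± 0.29 and the water channel Aqp1 at -0.98 ± 0.21. Distal convoluted and connecting tubule genes were lower in 3 of 9 (4 adjusted over the list alone), with a median of -0.40 (adjusted p = 0.0198, and adjusted p = 0.69 with an estimated correlation), among them the magnesium channel Trpm6 (-0.96 ± 0.13). This call was lost without the first (adjusted p = 0.0764) or the third 48 h kidney (0.0782), or without the second sham kidney (0.0909), and the median was -0.201 without the third and -0.69 without the second 48 h kidney. Fatty acid oxidation genes, with 3 of 21 lower (5, with 1 higher, adjusted over the list alone) and a median of -0.18, did not pass (adjusted p = 0.0641), but did without the first sham kidney (adjusted p = 0.0423) or the third 48 h kidney (0.0106), with no intensity filter (0.0499), with the replicate number as a block (0.048) and without the third kidneys at 48 h and 7 d (0.00702). Nor did the respiratory chain list, with 0 of 16 called (limma, 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone) and a median of -0.085 (adjusted p = 0.422). The thick ascending limb (median -0.55, adjusted p = 0.231) and collecting duct lists (-0.22, adjusted p = 0.132) passed, of the settings run, only without the second 48 h kidney (adjusted p = 0.0066 and 0.0115). Egf, made in the thick ascending limb and distal tubule, was lower at -2.64 ± 0.68. Endothelial markers were lower in 2 of 14 (2 adjusted over the list alone), Tek (-0.99 ± 0.20) and Ehd3 (-0.72 ± 0.19), with a median of -0.38 (adjusted p = 0.0116, and adjusted p = 0.779 with an estimated correlation). Without the third sham kidney this list's adjusted p was 0.134 (median -0.177), and without the first 48 h kidney 0.102 (median -0.246), while the median was -0.717 without the second sham kidney and -0.659 without the third 48 h kidney. Slc34a1 (-0.47 ± 0.21, adjusted p = 0.145) and Umod (-0.03 ± 0.19, adjusted p = 0.932) were not called. The Slc34a1 log2 values at 48 h were 15.5, 15.5 and 14.53, so its change rested mostly on the third kidney. Egf was not called without the first (adjusted p = 0.0605), the second (0.0576) or the third (0.0587) sham kidney or the first (0.0674) or the third (0.0599) 48 h kidney. Ehd3 lost its call without the first (0.0767) or the third (0.086) sham kidney or the first (0.0875) or the second (0.0642) 48 h kidney. Mep1b was not called without the first (0.0576) or the second (0.0673) sham kidney or the first (0.0531) or the third (0.086) 48 h kidney. Slc22a19 lost its call without the second (0.0526) sham kidney or the third (0.0635) 48 h kidney. Over the other settings the highest adjusted p was 0.0729 for Egf and 0.0679 for Ehd3.

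In all, 1284 genes were higher and 985 lower at 48 h than in sham, of which 312 and 156 by at least 2-fold. Without the third 48 h kidney 710 were higher and 427 lower, without the first 776 and 561, and without the third sham kidney 642 were lower. A fit of the 2 groups alone gave 578 lower, and one without the third kidneys at 48 h and 7 d 575 lower. Sham and 48 h lay on different BeadChips. Among 18967 probes too dim for the intensity filter, 127 were called between 48 h and sham, against 0 between 6 h and sham (limma, with 15.6% and 5.41% of these probes at an unadjusted p under 0.05).

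**Figure D3:**
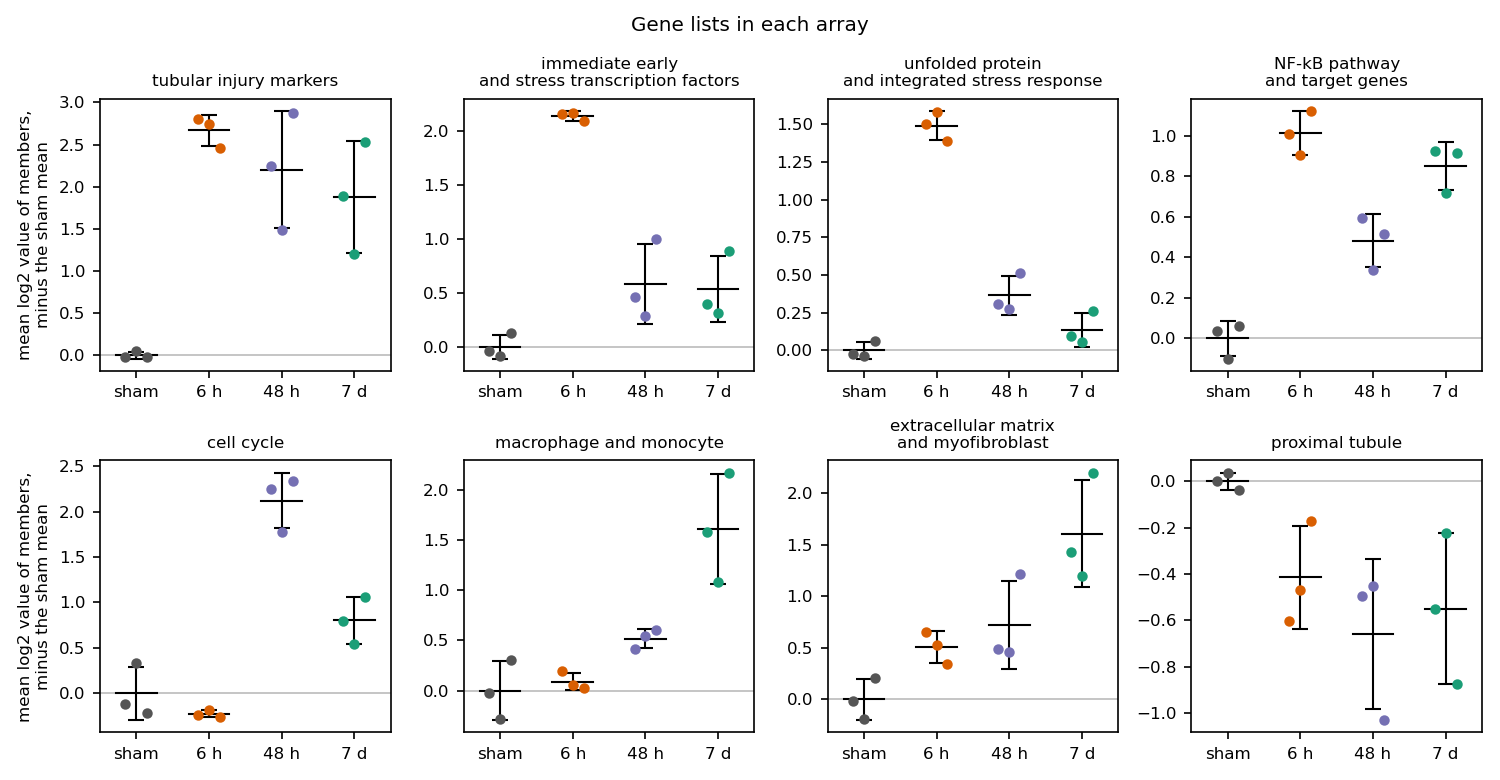
Mean log2 value of the measured members of 8 gene lists in each kidney, minus the sham mean, with 1 point per kidney, horizontal lines for group means and bars for 1 SD (n = 3). The stress lists are highest at 6 h, cell cycle genes at 48 h (2.12 ± 0.31), and macrophage (1.61 ± 0.55) and matrix genes (1.61 ± 0.52) at 7 d.

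At 7 d, genes of matrix and of macrophages were higher than in sham, and injury markers were still raised. Of 22 extracellular matrix and myofibroblast genes, 17 were higher (19 adjusted over the list alone), with a median log2 change of 1.53 (camera, adjusted p = 2.05e-12, and adjusted p = 0.456 with an estimated correlation). The collagen genes Col3a1 and Col1a1 were higher by 2.76 ± 0.27 and 2.64 ± 0.24, the gelatinase Mmp2 by 2.61 ± 0.21 and the proteoglycan lumican, Lum, by 0.92 ± 0.08. Of 18 macrophage and monocyte markers 15 were higher (17 adjusted over the list alone), with a median of 1.27 (adjusted p = 2.09e-12, and adjusted p = 0.407 with an estimated correlation), including Mpeg1 (2.58 ± 0.30), Cd14 (2.29 ± 0.25), Cx3cr1 (1.18 ± 0.16) and the protease Ctss (1.09 ± 0.12). Of 9 dendritic cell and MHC class II genes 7 were higher (7, with 1 lower, adjusted over the list alone), with a median of 1.72 (adjusted p = 0.000362, and adjusted p = 0.456 with an estimated correlation), including H2-Ab1 (2.21 ± 0.38) and the invariant chain gene Cd74 (2.16 ± 0.41). Interferon response genes were higher in 10 of 20 (13 adjusted over the list alone), with a median of 0.46 (adjusted p = 4.85e-05, and adjusted p = 0.52 with an estimated correlation), including Gbp2 (1.35 ± 0.27), Ifit2 (0.93 ± 0.17) and B2m (0.78 ± 0.11).

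The largest increases at 7 d were in Lcn2 (4.74 ± 0.72), Havcr1 (4.62 ± 0.51), the lysozyme genes Lyz1 (4.56 ± 0.52) and Lyz2 (3.65 ± 0.56), the diamine oxidase Aoc1 (3.89 ± 0.38), Serpina10 (3.85 ± 0.54), Timp1 (3.69 ± 0.53) and Vcam1 (3.42 ± 0.26), with adjusted p of 0.00244 or less. Lyz1 and Lyz2 are close paralogs. Other probes of Vcam1 gave 0.46 and 1.08. Tubular injury markers were higher in 12 of 18 (14 adjusted over the list alone), with a median of 1.53 (adjusted p = 5.76e-09, and adjusted p = 0.498 with an estimated correlation). Genes of the NF-κB list were higher in 23 of 34 (26, with 1 lower, adjusted over the list alone), with a median of 0.68 (adjusted p = 3.74e-12, and adjusted p = 0.271 with an estimated correlation). Besides Vcam1 they included Tlr2, a receptor of bacterial lipoproteins (2.08 ± 0.16), Relb (1.27 ± 0.13), Cd83 (0.99 ± 0.11), Tnfaip3 (0.78 ± 0.09), Ccl2 (0.82 ± 0.19) and Nfkbia (0.54 ± 0.17). Nfkbia was not called without the first (adjusted p = 0.103) or the second (0.147) sham kidney or the first (0.149) or the third (0.11) 7 d kidney. Ccl2 lost its call without the first (0.0544) or the third (0.0511) 7 d kidney. Over the other settings the highest adjusted p was 0.104 for Nfkbia. Cell cycle genes were higher in 18 of 25 (21 adjusted over the list alone), with a median of 0.78 (adjusted p = 1.64e-09, and adjusted p = 0.507 with an estimated correlation). Acute phase genes were higher in 8 of 16 (10, with 2 lower, adjusted over the list alone), with a median of 0.83 (adjusted p = 0.000822, and adjusted p = 0.488 with an estimated correlation). Immediate early genes were higher in 7 of 21 (8 adjusted over the list alone), with a median of 0.31 (adjusted p = 0.0291, and adjusted p = 0.779 with an estimated correlation), and Junb was higher by 1.87 ± 0.36. This call was lost without the third 7 d kidney (adjusted p = 0.166) or the first sham kidney (adjusted p = 0.0764).

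The largest decreases at 7 d were in the lipid transporter Mfsd2a (-2.70 ± 0.54), Cyp7b1 (-2.67 ± 0.85), Serpina1d (-2.65 ± 0.69), Slc22a13 (-2.00 ± 0.55), the peroxisomal oxidase Acox2 (-1.97 ± 0.35), Azgp1 (-1.91 ± 0.40), the uridine phosphorylase Upp2 (-1.90 ± 0.40) and Sec14l3 (-1.89 ± 0.51), with adjusted p of 0.0473 or less. Proximal tubule genes were lower in 8 of 33 (10 adjusted over the list alone), with a median of -0.58 (adjusted p = 3.41e-05, and adjusted p = 0.581 with an estimated correlation), including the gluconeogenic enzyme Fbp1 (-1.32 ± 0.33). Without the third 7 d kidney this median was -0.356. Genes of fatty acid oxidation and peroxisomes were lower in 6 of 21 and higher in 1 (7 and 1 adjusted over the list alone), with a median of -0.32 (adjusted p = 0.00178, and adjusted p = 0.498 with an estimated correlation). Without the third 7 d kidney this median was -0.199. The acyl-CoA dehydrogenases Acadm (-0.89 ± 0.24) and Acadl (-0.79 ± 0.15) were lower, and Cpt1a, which admits fatty acids to mitochondria, was higher (0.31 ± 0.08). Slc34a1 (-0.09 ± 0.21, adjusted p = 0.777) and Umod (-0.11 ± 0.19, adjusted p = 0.717) were not called. Cyp7b1 was not called without the first (adjusted p = 0.0964), the second (0.121) or the third (0.0804) sham kidney or the first (0.118) or the third (0.159, with a change of -1.72) 7 d kidney. Serpina1d lost its call without the first (0.0514) or the second (0.0655) sham kidney or the first (0.0603) or the third (0.0847) 7 d kidney. Slc22a13 was not called without the second (0.0832) or the third (0.0679) sham kidney or the first (0.0577) or the third (0.0925) 7 d kidney. Sec14l3 lost its call without the first (0.0626) or the second (0.0731) sham kidney or the first (0.0894) or the third (0.0909) 7 d kidney. Fbp1 was not called without the second (0.0519) or the third (0.0514) sham kidney or the first (0.0609) or the third (0.0527) 7 d kidney. Acadm lost its call without the first (0.0557) or the second (0.0894) sham kidney or the first (0.0945) or the third (0.0981) 7 d kidney. Cpt1a was not called without the second (0.0795) sham kidney or the first (0.07) or the third (0.0928) 7 d kidney. Over the other settings the highest adjusted p was 0.0791 for Cyp7b1, 0.0596 for Sec14l3, 0.0568 for Fbp1, 0.0713 for Acadm and 0.0853 for Cpt1a.

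In all, 1612 genes were higher and 1129 lower at 7 d than in sham, of which 369 and 126 by at least 2-fold. Without the first 7 d kidney 859 were higher and 448 lower, without the third 844 and 467, and without the second sham kidney 1051 and 632. A fit of the 2 groups alone gave 1011 and 609, one without the third kidneys at 48 h and 7 d 659 lower, and one with array weights 2557 and 2044. These groups lay on different BeadChips, and 274 of the dim probes were called.

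Between 6 h and 48 h immediate early, unfolded protein and heat shock genes fell and cell division genes rose. All 25 cell cycle genes were higher at 48 h than at 6 h (25 adjusted over the list alone), with a median log2 difference of 2.44 (camera, adjusted p = 2.31e-25, and adjusted p = 0.3 with an estimated correlation). The largest increases were in Prc1 (4.22 ± 0.38), the histone genes H2ac22 (3.93 ± 0.30), H2ac24 (3.89 ± 0.32), H2ac7 (3.84 ± 0.27) and H2ac15 (3.66 ± 0.26), Cdc20 (3.73 ± 0.22), the mitotic kinase Pbk (3.51 ± 0.30) and Cenpa (3.48 ± 0.21), with adjusted p of 2.31e-05 or less. Immediate early genes were lower in 18 of 21 (20 adjusted over the list alone), with a median of -1.55 (adjusted p = 2.61e-15, and adjusted p = 0.294 with an estimated correlation). Genes of the unfolded protein and integrated stress response were lower in 9 of 15 and higher in 2 (10 and 2 adjusted over the list alone), with a median of -0.91 (adjusted p = 2.45e-06, and adjusted p = 0.271 with an estimated correlation). Heat shock genes were lower in 7 of 14 (10 adjusted over the list alone), with a median of -0.49 (adjusted p = 3.89e-06, and adjusted p = 0.294 with an estimated correlation). Oxidative stress genes, with 6 of 14 lower and 3 higher (7 and 3 adjusted over the list alone) and a median of -0.33, did not pass (adjusted p = 0.12), but did without the third 48 h kidney (0.008) and without the third kidneys at 48 h and 7 d (0.00693). Nor did p53 targets, with 5 of 14 lower and 2 higher (5 and 2 adjusted over the list alone) and a median of -0.26 (adjusted p = 0.0676), which passed without the third 6 h kidney (0.0465) or the third 48 h kidney (0.023), with fry (0.0249), with no intensity filter (0.0414), with the replicate number as a block (0.0465) and without the third kidneys at 48 h and 7 d (0.00975). The largest decreases were in Chac1 (-4.47 ± 0.25), Angptl7 (-3.61 ± 0.33), Cyp2d9 (-3.54 ± 0.74), Dnase1 (-3.54 ± 0.68), Hmox1 (-3.39 ± 0.28), Inmt (-3.38 ± 0.72), the pyruvate dehydrogenase kinase Pdk4 (-3.36 ± 0.43) and the sphingosine kinase Sphk1 (-3.32 ± 0.32), with adjusted p of 0.00602 or less.

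Genes of the NF-κB list were lower at 48 h than at 6 h in 15 of 34 and higher in 1 (19 and 2 adjusted over the list alone), with a median of -0.48 (adjusted p = 5.83e-06, and adjusted p = 0.456 with an estimated correlation). Without the third 6 h kidney this median was -0.312. Cxcl1 differed by -3.23 ± 0.38, Cxcl2 by -2.54 ± 0.24, Nfkbia by -1.47 ± 0.17, Il6 by -1.17 ± 0.08, Rela by -1.15 ± 0.12 and Tnfaip3 by -1.09 ± 0.09. Vcam1 was higher at 48 h, by 1.47 ± 0.26. Neutrophil markers were lower in 4 of 13 (5 adjusted over the list alone), with a median of -0.089 (adjusted p = 0.0121, and adjusted p = 0.498 with an estimated correlation), among them S100a8 (-2.30 ± 0.36) and S100a9 (-2.12 ± 0.24). The median of this list was -0.146 without the third 6 h kidney, and -0.0591 and -0.17 without the second and without the third 48 h kidney. Havcr1 (0.66 ± 0.51, adjusted p = 0.385) and Lcn2 (-0.28 ± 0.72, adjusted p = 0.816) were not called between these times. In all, 1880 genes were higher and 1424 lower at 48 h than at 6 h, of which 325 and 278 by at least 2-fold. Array weights gave 2173 lower. The groups lay on different BeadChips, and 132 of the dim probes were called.

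From 48 h to 7 d, both on 1 BeadChip, cell division genes fell and genes of antigen presentation, macrophages and matrix rose. Cell cycle genes were lower at 7 d in 23 of 25 (25 adjusted over the list alone), with a median log2 difference of -1.33 (camera, adjusted p = 5.92e-30, and adjusted p = 0.271 with an estimated correlation). The largest decreases were in Cdca3 (-2.67 ± 0.25), Cdkn3 (-2.56 ± 0.29), Cdc20 (-2.25 ± 0.22), Krt20 (-2.11 ± 0.41), Birc5 (-2.10 ± 0.22), the vitamin D hydroxylase Cyp24a1 (-2.10 ± 0.35), Tk1 (-2.07 ± 0.22) and Mad2l1 (-1.94 ± 0.22), with adjusted p of 0.013 or less. The largest increases were in Cd74 (3.13 ± 0.41), the MHC class II genes H2-Eb1 (2.92 ± 0.44), H2-Ab1 (2.88 ± 0.38) and H2-Aa (2.83 ± 0.39), Fcrls (2.76 ± 0.58), Mmp2 (2.49 ± 0.21), Apoe (2.38 ± 0.38) and Lyz2 (2.27 ± 0.56), with adjusted p of 0.0376 or less. Dendritic cell and MHC class II genes were higher in 7 of 9 (8 adjusted over the list alone), with a median of 1.42 (adjusted p = 1.5e-08, and adjusted p = 0.271 with an estimated correlation). Macrophage markers were higher in 14 of 18 (14, with 1 lower, adjusted over the list alone), with a median of 1.07 (adjusted p = 6.66e-12, and adjusted p = 0.407 with an estimated correlation), including the receptor gene Csf1r (1.53 ± 0.21) and Mpeg1 (1.89 ± 0.30). Matrix genes were higher in 9 of 22 (13 adjusted over the list alone), with a median of 0.97 (adjusted p = 3.95e-09, and adjusted p = 0.498 with an estimated correlation), including fibronectin, Fn1 (2.07 ± 0.36). Genes of the NF-κB list were higher in 7 of 34 (11 adjusted over the list alone), with a median of 0.24 (adjusted p = 7.26e-06, and adjusted p = 0.456 with an estimated correlation), including Vcam1 (1.68 ± 0.26), Tlr2 (1.25 ± 0.16), Cd83 (1.03 ± 0.11) and Tnfaip3 (0.55 ± 0.09). Oxidative stress genes were lower in 3 of 14 (7 adjusted over the list alone), with a median of -0.50 (adjusted p = 3.26e-05, and adjusted p = 0.456 with an estimated correlation), with Nqo1 at -1.38 ± 0.16. Without the third 48 h kidney this median was -0.265. Havcr1 (-0.79 ± 0.51, adjusted p = 0.42) and Lcn2 (-0.76 ± 0.72, adjusted p = 0.612) were not called. Lyz2 was not called without the first (adjusted p = 0.13), the second (0.0856) or the third (0.0513) 48 h kidney or the first (0.0784) or the third (0.0667) 7 d kidney. Fcrls lost its call without the first (0.0668) or the third (0.055) 48 h kidney or the first (0.0772) or the third (0.0609) 7 d kidney. Krt20 was not called without the first (0.0537) 48 h kidney. In a fit of these 6 arrays alone, Vcam1 (0.0612), Tnfaip3 (0.0595), Fn1 (0.0754), Fcrls (0.0595), Krt20 (0.0949) and Lyz2 (0.122) were not called.

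In all, 429 genes were higher and 395 lower at 7 d than at 48 h, of which 108 and 81 by at least 2-fold. A fit of these 6 arrays alone gave 137 higher and 134 lower, one without the third kidneys of both times 210 and 204, and one with array weights 1743 and 1490. Without the first 48 h kidney 131 were higher and 152 lower, without the first 7 d kidney 158 and 180, without the third 7 d kidney 227 were higher, and without the third 48 h kidney 245 were lower.

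Many genes were called at more than one time against sham. At all 3 times 243 genes were higher and 224 lower. At 6 h and 48 h, 421 genes were higher in both, against 154 for independent lists of these sizes, and 406 lower in both, against 126. For 6 h and 7 d the shared calls were 402 higher (194 for independent lists) and 328 lower (145). For 48 h and 7 d they were 645 higher (152) and 552 lower (81.6). In opposite directions, 20 genes were higher at 6 h and lower at 48 h (118 for independent lists) and 64 lower and then higher (164). These numbers were 44 (136) and 104 (206) for 6 h and 7 d, and 3 (106) and 0 (116) for 48 h and 7 d. Groups simulated with no effect against the same sham arrays shared 0.01 calls or fewer on average. No gene was changed in that simulation, so almost none was called. It cannot show how many shared calls the sham arrays add where many genes change. Log2 changes across genes, which are not independent replicates, correlated at r = 0.494 between 6 h and 48 h, 0.381 between 6 h and 7 d and 0.738 between 48 h and 7 d, against 0.50 from the shared sham arrays alone in groups simulated with no effect. The covariances were 0.112, 0.0854 and 0.146, against 0.0119 in the simulation. Part of the overlap may come from the shared sham arrays, which are too few to split, and for 48 h and 7 d also from the shared BeadChip.

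Of the 155 list tests over 31 lists and 5 comparisons, 51 were called with the preset correlation, 0 of these with an estimated correlation (camera, with 16 of the 155 at an unadjusted p under 0.05) and 37 with fry, which tests whether the genes of a list move one way and does not compare the list with other genes. With fry the calls lost were collecting duct and proximal tubule at 6 h, distal tubule, endothelium, matrix, immediate early genes and macrophages at 48 h, and immediate early genes and proximal tubule at 7 d. Between times they were endothelium from 6 h to 48 h, and endothelium, erythroid, heat shock and interferon genes from 48 h to 7 d. Of 278 called values of named genes, 53 were smaller and 1 larger by over 1.5 times with the mean of all probes of a gene, 28 were larger with normexp background correction and 3 smaller without the third kidneys at 48 h and 7 d.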

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

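Among the tests in this part, those of differences in injury, array noise and tissue share, those of genes called within a BeadChip and those of infiltrating cells were chosen only after the result was seen.

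Several lists differed between times. From 6 h to 48 h the median log2 difference was -0.48 for the NF-κB list, -1.55 for immediate early genes, -0.49 for heat shock proteins, -0.91 for the unfolded protein response, 2.44 for cell cycle genes, -0.40 for endothelium and -0.089 for neutrophil markers. From 48 h to 7 d it was 0.24 for the NF-κB list, -0.19 for heat shock proteins, -0.50 for oxidative stress, 0.55 for interferon response, -1.33 for cell cycle genes, 0.97 for matrix, 0.45 for endothelium, 1.07 for macrophages, 1.42 for MHC class II and -2.73 for erythroid genes. Each passed camera with the preset correlation and none with an estimated correlation. The endothelium call from 6 h to 48 h was lost without the first 6 h kidney (adjusted p = 0.0664) or the first 48 h kidney (0.0772), and the erythroid call from 48 h to 7 d without the first 7 d kidney (0.0629). From 6 h to 48 h the median was -0.312 for the NF-κB list without the third 6 h kidney, -0.187 and -0.608 for endothelium without the first and without the third 48 h kidney, and -0.146, -0.0591 and -0.17 for neutrophil markers without the third 6 h, the second 48 h and the third 48 h kidney. From 48 h to 7 d it was -0.265 for oxidative stress without the third 48 h kidney, 0.234 for endothelium without the first 48 h kidney and -1.82 and -4.03 for erythroid genes without the third and without the second 7 d kidney.

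Against sham, 84 genes were called in opposite directions at 6 h and at 48 h with the difference between these times called too, among them Selenoh (-0.90 and 1.74) and Spag5 (-1.09 and 1.18). Between 48 h and 7 d this held for 3 genes, Ppa1 (0.37 and -0.33), Ttc19 (0.34 and -0.36) and Wars (0.29 and -0.45), which like Selenoh and Spag5 were named after their values were seen. All 3 lost the call at 48 h without the third 48 h kidney (adjusted p = 0.144, 0.0719 and 0.069), the first sham kidney (0.0617, 0.0599 and 0.0768) or the third sham kidney (0.115, 0.0571 and 0.0608). So did Ppa1 and Wars without the first 48 h kidney (0.0671 and 0.0697) and Ppa1 without the second sham kidney (0.0568). At 7 d Ppa1 lost its call on leaving out the first, the second or the third 7 d kidney (0.148, 0.0573 and 0.115) or the first, the second or the third sham kidney (0.116, 0.128 and 0.0516), and Ttc19 lost it without the first 7 d kidney (0.0609). Over 15 other settings at the same threshold, Ppa1, Ttc19 and Wars lost the call at 48 h in 6, 4 and 6 (adjusted p up to 0.155, 0.0697 and 0.203) and at 7 d in 9, 2 and 1 (up to 0.101, 0.134 and 0.111). Of 4091 probes that passed the intensity filter and carry no gene symbol, 699 were called at 6 h, 717 at 48 h and 711 at 7 d against sham.

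The 3 kidneys at 48 h and the 3 at 7 d were spread along 1 axis that held 76.1% and 81% of the spread within each group, against 71.7% in sham and 73.7% at 6 h. Changes along the axis correlated across genes with the 6 h change, measured on other arrays, at r = 0.52 at 48 h and 0.409 at 7 d, which argues against noise that is independent between arrays, and over dim probes the SD of array differences at 48 h and 7 d was 1.0232 times that at sham and 6 h. Along the axis the other tubule segments fell with the proximal tubule and did not rise. Their median was -0.564 at 48 h (95% interval over members -0.794 to -0.435) and -0.348 at 7 d (-0.429 to -0.252). This argues against a smaller share of proximal tubule as the only cause. As a part of the spread it stays open, since a fall in all segments would hide it. The intervals do not measure the spread between kidneys. Animals may have differed in the extent of injury, and along the axis the injury list spanned a median of 1.24 and 1.26 on the log2 scale, Havcr1 0.989 and 2.22 and Lcn2 2.75 and 2.69. Noise or handling that shifts the same genes on several arrays was not tested. The axis of the sham kidneys had an r of 0.00224 with the 6 h change, but 0.338 with the 7 d minus 48 h change, measured on other arrays. Kidneys with no clamp thus also spread along an axis shared with a change on other arrays. Such an r does not by itself point to the extent of injury.

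BeadChip and group cannot be told apart for 48 h and 7 d against sham. Calls for 6 h against sham and 7 d against 48 h lay within a BeadChip. Over probes below the intensity filter, the 48 h minus 6 h and 7 d minus sham differences correlated at r = 0.476. These share no array, and differences within a BeadChip gave -0.0965. A BeadChip difference (log2 SD 0.0605, no bound for brighter genes) or a lasting late change could give this. Of 354 genes called at 48 h against sham and from 48 h to 7 d, 330 went opposite ways, but both differences use the 48 h arrays, and when the first, the second or the third 48 h kidney was kept out of the calls from 48 h to 7 d and set alone against sham, 74.9%, 72.6% and 54.9% of the genes called went the other way, against 50% for independent directions. Of genes called at 6 h without the first, the second or the third sham kidney, 77.1%, 63.8% and 72.8% lay the same way at 48 h against that kidney and 71.4%, 55.6% and 65.1% at 7 d. Since 2 of these shares lay close to 50%, a BeadChip difference stays open for calls at 48 h and 7 d against sham. Among them are the 616 of 1197 genes called the same way at both times and neither at 6 h nor between them.

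The NF-κB list rose at 6 h by a median of 0.77 and from 48 h to 7 d by 0.24. At 6 h the macrophage list had a median of 0.0311 (95% interval over members -0.216 to 0.133). Its mean spanned -0.283 to 0.304 over sham kidneys and Cd14 rose, so RNA of infiltrating macrophages stays open. So do neutrophils, whose list had a median of 0.204 (-0.0128 to 0.65) while S100a8 and S100a9 rose. From 48 h to 7 d the macrophage list rose by 1.07 (0.748 to 1.67), and infiltrating macrophages could be part of the later rise. Tubular cells were not measured apart from other kidney cells.

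Arrays were regrouped for each count. With 3 kidneys against 3 there were 10 splits, too few for a share under 0.05, and in each only the real split gave as many genes. The real splits gave 3608, 1465 and 1620 genes for 6 h, 48 h and 7 d against sham, 3319 for 48 h against 6 h and 271 for 7 d against 48 h, and the others at most 0, 0, 0, 0 and 2. For the F test 1 of 100 splits of the 12 arrays, the real one, gave as many as 6079 genes (highest other 140). Chance is unlikely there, but a BeadChip difference may add to the count.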

How the results depend on the processing

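The normexp background correction and the fit without the third kidneys at 48 h and 7 d were chosen only after the data had been seen, and the other settings before. No called result turned its direction in any setting. Among results not called, the direction turned in 18 values of lists and 7 of named genes over the settings other than leaving out 1 kidney, and in 39 and 11 when 1 kidney was left out. Over the settings other than leaving out 1 kidney, 5488 values of named genes kept their direction and their side of the threshold, 196 lost a call and 54 gained one. When 1 kidney was left out these numbers were 1843, 155 and 25. The counts below are given as higher and lower, and the list values are median log2 changes with the adjusted p in parentheses. The cause of each change was not tested except where a stricter threshold accounts for it. No detection p-value was used, and changes of probes near the lowest intensity are compressed by the unsubtracted background.

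At an adjusted p under 0.01 the F test called 3375 genes. The counts at that threshold were 976 and 831 for 6 h against sham, 544 and 288 for 48 h against sham, 590 and 273 for 7 d against sham, 1018 and 728 for 48 h against 6 h and 99 and 125 for 7 d against 48 h. With a change of at least 2-fold they were 454 and 228 for 6 h against sham, 312 and 156 for 48 h against sham, 369 and 126 for 7 d against sham, 325 and 278 for 48 h against 6 h and 108 and 81 for 7 d against 48 h. Array weights gave 2557 and 2044 for 7 d against sham, 1743 and 1490 for 7 d against 48 h and 2173 lower for 48 h against 6 h. Fits of the 2 groups compared had fewer arrays and a variance of their own. They gave 578 lower for 48 h against sham and 1011 and 609 for 7 d against sham. For 7 d against 48 h they gave 137 and 134. For 6 h against sham such a fit gave 1663 and 1945, no fewer than reported. Between arrays of a group the SD of differences over tested genes was 0.162 to 0.253 at 6 h and 0.218 to 0.325 in sham. It was 0.237 to 0.386 at 48 h and 0.263 to 0.412 at 7 d. The variance shared by all groups can thus be too small for 48 h and 7 d. Without the third kidneys at 48 h and 7 d the counts were 575 lower for 48 h against sham, 659 lower for 7 d against sham and 210 and 204 for 7 d against 48 h. Under the other normalizations, offsets, filters, probe rule, variance model and background correction every count stayed within 1.5 times that reported. Leaving out 1 kidney at a time gave 1152 to 1591 higher and 1080 to 1623 lower for 6 h against sham, 710 to 1372 higher and 427 to 1069 lower for 48 h against sham, 844 to 1793 higher and 448 to 1272 lower for 7 d against sham, 1291 to 1660 higher and 965 to 1309 lower for 48 h against 6 h and 131 to 571 higher and 152 to 438 lower for 7 d against 48 h, and 4681 to 6106 in the F test.

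The replicate numbers of the labels were not taken as a pairing. Deviations from the group means of kidneys with the same number correlated at 0.09, -0.039 and -0.29 for 6 h against sham, -0.083, 0.0093 and 0.13 for 48 h against sham, 0.035, 0.085 and 0.089 for 7 d against sham, -0.23, -0.15 and -0.35 for 48 h against 6 h and -0.098, 0.47 and 0.57 for 7 d against 48 h. Every kidney correlated best with its own number only in 7 d against sham (6 of 6), against 1 for 6 h against sham, 2 for 48 h against sham, 0 for 48 h against 6 h and 4 for 7 d against 48 h, a hint from the data and not from the design. With the replicate number as a block the counts were 1581 and 1700 for 6 h against sham, 1206 and 914 for 48 h against sham, 1539 and 1024 for 7 d against sham, 1798 and 1360 for 48 h against 6 h and 391 and 328 for 7 d against 48 h, and 5689 in the F test. Shared with the fit without the block were 3137 of 3383 calls, 1974 of 2269 calls, 2404 of 2741 calls, 3001 of 3304 calls and 670 of 824 calls in the same order. The block added list calls, for 6 h against sham matrix 0.51 (0.0397), for 48 h against sham fatty acid oxidation -0.18 (0.048), for 48 h against 6 h p53 -0.26 (0.0465) and regeneration -0.42 (0.0455) and for 7 d against 48 h unfolded protein -0.13 (0.048), and ended none.

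With an estimated correlation no list call held. The medians of these lists for 6 h against sham were NF-κB 0.77, acute phase 0.70, collecting duct -0.32, heat shock 0.84, immediate early 1.96, neutrophil 0.20, oxidative stress 0.76, p53 0.44, proximal tubule -0.38, tubular injury 2.40 and unfolded protein 0.92. For 48 h against sham they were NF-κB 0.36, acute phase 0.51, cell cycle 2.26, distal tubule -0.40, endothelium -0.38, matrix 0.67, immediate early 0.44, macrophage 0.36, oxidative stress 0.58, proximal tubule -0.71, tubular injury 1.93 and unfolded protein 0.26. For 7 d against sham they were NF-κB 0.68, acute phase 0.83, cell cycle 0.78, MHC class II 1.72, matrix 1.53, fatty acid oxidation -0.32, immediate early 0.31, interferon 0.46, macrophage 1.27, proximal tubule -0.58 and tubular injury 1.53. For 48 h against 6 h they were NF-κB -0.48, cell cycle 2.44, endothelium -0.40, heat shock -0.49, immediate early -1.55, neutrophil -0.089 and unfolded protein -0.91. For 7 d against 48 h they were NF-κB 0.24, cell cycle -1.33, MHC class II 1.42, endothelium 0.45, erythroid -2.73, matrix 0.97, heat shock -0.19, interferon 0.55, macrophage 1.07 and oxidative stress -0.50.

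With fry the calls lost were, for 6 h against sham collecting duct -0.32 (0.0696) and proximal tubule -0.38 (0.158), for 48 h against sham distal tubule -0.40 (0.102), endothelium -0.38 (0.202), matrix 0.67 (0.129), immediate early 0.44 (0.101) and macrophage 0.36 (0.224), for 7 d against sham immediate early 0.31 (0.162) and proximal tubule -0.58 (0.101), for 48 h against 6 h endothelium -0.40 (0.118), for 7 d against 48 h endothelium 0.45 (0.171), erythroid -2.73 (0.129), heat shock -0.19 (0.0825) and interferon 0.55 (0.0692). The calls gained there were, for 6 h against sham regeneration -0.055 (0.00211, called as higher), for 48 h against sham cell death 0.16 (0.036), for 7 d against sham adrenal -0.16 (0.036), hypoxia -0.13 (0.0337) and cell death 0.079 (0.00522), for 48 h against 6 h p53 -0.26 (0.0249) and regeneration -0.42 (0.00211), for 7 d against 48 h T and NK cell 0.14 (0.035). Without the third kidneys at 48 h and 7 d the calls lost were, for 48 h against sham distal tubule -0.20 (0.0618) and unfolded protein 0.19 (0.0526), for 7 d against sham immediate early 0.25 (0.0552), for 7 d against 48 h erythroid -1.75 (0.0597). The calls gained there were, for 6 h against sham matrix 0.51 (0.0105) and thick ascending limb -0.71 (0.0289), for 48 h against sham fatty acid oxidation -0.25 (0.00702), for 48 h against 6 h oxidative stress -0.49 (0.00693), p53 -0.34 (0.00975), regeneration -0.27 (0.0485) and tubular injury -0.55 (0.00232), for 7 d against 48 h tubular injury -0.49 (0.0194). With no intensity filter the calls gained were, for 6 h against sham matrix 0.51 (0.0364) and thick ascending limb -0.71 (0.039), for 48 h against sham fatty acid oxidation -0.18 (0.0499), for 48 h against 6 h p53 -0.14 (0.0414), for 7 d against 48 h T and NK cell 0.13 (0.0277) and unfolded protein -0.13 (0.0279). With normexp background correction the calls gained were, for 6 h against sham thick ascending limb -0.88 (0.0447), for 7 d against sham erythroid -2.27 (0.0493), for 48 h against 6 h macrophage 0.54 (0.0493) and regeneration -0.44 (0.0486), for 7 d against 48 h unfolded protein -0.17 (0.0493). With the mean of all probes of a gene the calls gained were, for 6 h against sham thick ascending limb -0.71 (0.0497).

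The lists not called whose tested direction turned, which need not be the sign of the median, had these medians. With the mean of all probes these were, for 7 d against sham common reference genes -0.031 (0.944) and oxidative stress 0.045 (0.944), for 7 d against 48 h B cell and plasma cell -0.0074 (0.969). With the replicate block these were, for 48 h against 6 h common reference genes 0.028 (0.951). With fry these were, for 48 h against sham regeneration 0.12 (0.722), for 7 d against sham oxidative stress 0.073 (0.833), for 48 h against 6 h common reference genes 0.028 (0.954). With normexp these were, for 7 d against sham oxidative stress 0.11 (0.933), for 48 h against 6 h common reference genes 0.028 (0.952). With no intensity filter these were, for 48 h against sham perirenal fat -0.052 (0.925), for 7 d against sham oxidative stress 0.073 (0.979) and perirenal fat -0.061 (0.84). Without the third kidneys at 48 h and 7 d these were, for 7 d against sham common reference genes 0.050 (0.902), endothelium 0.026 (0.916) and oxidative stress 0.029 (0.876), for 48 h against 6 h matrix 0.13 (0.991), for 7 d against 48 h fatty acid oxidation 0.029 (0.926) and perirenal fat 0.023 (0.922). The genes, with their log2 changes, were Slc34a1 for 48 h against 6 h without the third kidneys at 48 h and 7 d 0.043, Umod for 48 h against 6 h with cyclic loess -0.045, Umod for 48 h against 6 h with the mean of all probes -0.10, Umod for 48 h against sham without the third kidneys at 48 h and 7 d 0.13, Umod for 7 d against 48 h with array weights 0.060, Umod for 7 d against sham with array weights 0.045 and Umod for 7 d against sham without the third kidneys at 48 h and 7 d 0.034. Leaving out 1 kidney at a time, those genes whose direction turned spanned -0.68 to 0.012 for Cd74 in 6 h against sham, -0.70 to 0.048 for Cxcl1 in 7 d against 48 h, -1.03 to 0.43 for Lcn2 in 48 h against 6 h, -0.44 to 0.043 for Slc34a1 in 48 h against 6 h, -0.21 to 0.20 for Umod in 48 h against 6 h, -0.28 to 0.13 for Umod in 48 h against sham, -0.24 to 0.17 for Umod in 7 d against 48 h and -0.19 to 0.034 for Umod in 7 d against sham.

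Leaving out 1 kidney at a time ended or added list calls or turned the direction of lists not called, and the lowest and highest medians over these fits follow. For 6 h against sham these were B cell and plasma cell -0.074 to 0.016, T and NK cell -0.068 to 0.078, cell cycle -0.28 to -0.0012, collecting duct -0.35 to -0.26, endothelium -0.039 to 0.30, matrix 0.39 to 0.65, interferon -0.058 to 0.17, macrophage -0.077 to 0.11, podocyte -0.021 to 0.15 and proximal tubule -0.41 to -0.30. For 48 h against sham these were T and NK cell -0.082 to 0.023, collecting duct -0.33 to -0.12, MHC class II -0.20 to -0.11, distal tubule -0.69 to -0.20, endothelium -0.72 to -0.18, erythroid -0.33 to 0.99, fatty acid oxidation -0.28 to -0.18, heat shock -0.012 to 0.13, hypoxia -0.10 to 0.067, macrophage 0.24 to 0.47, thick ascending limb -0.68 to -0.35 and unfolded protein 0.19 to 0.35. For 7 d against sham these were common reference genes 0.0053 to 0.12, endothelium -0.18 to 0.21, erythroid -3.53 to -1.31, hypoxia -0.20 to -0.051, immediate early 0.25 to 0.41 and oxidative stress -0.063 to 0.17. For 48 h against 6 h these were acute phase -0.28 to -0.031, common reference genes -0.079 to 0.038, distal tubule -0.41 to 0.082, endothelium -0.61 to -0.19, matrix 0.13 to 0.35, interferon -0.060 to 0.15, oxidative stress -0.49 to -0.23, p53 -0.34 to -0.20, proximal tubule -0.27 to -0.072, regeneration -0.47 to -0.18, respiratory chain and citric acid cycle -0.031 to 0.16, thick ascending limb -0.046 to 0.46 and tubular injury -0.55 to 0.16. For 7 d against 48 h these were B cell and plasma cell -0.082 to 0.024, collecting duct -0.0037 to 0.25, distal tubule 0.11 to 0.66, erythroid -4.03 to -1.82, fatty acid oxidation -0.24 to -0.011, immediate early -0.20 to 0.19, neutrophil 0.014 to 0.11, p53 -0.13 to -0.015, perirenal fat -0.062 to 0.0046, podocyte -0.033 to 0.070, proximal tubule -0.093 to 0.28, respiratory chain and citric acid cycle -0.16 to 0.035, thick ascending limb 0.0061 to 0.42, tubular injury -0.79 to -0.057 and unfolded protein -0.19 to -0.14.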

Other observations

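The test of male-biased genes was chosen only after the result was seen.

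Genes of the endothelium went both ways at 6 h, when 2 of 14 rose and 3 fell (3 and 3 adjusted over the list alone), with a median log2 change of 0.14 (camera, adjusted p = 0.601). The nitric oxide synthase Nos3 rose by 1.71 ± 0.16 (SE of the 12-array fit, 3 against 3 kidneys) and the junction protein Cdh5 by 0.65 ± 0.11. The angiopoietin receptor Tek fell by 1.31 ± 0.20 on the log2 scale. Between 6 h and 48 h, Nos3 and Cdh5 differed by -1.58 ± 0.16 and -0.94 ± 0.11, and 4 of 14 were lower (6 adjusted over the list alone), with a median of -0.40 (adjusted p = 0.0143, and adjusted p = 0.779 with an estimated correlation). This call was lost without the first 6 h kidney (adjusted p = 0.0664) or the first 48 h kidney (0.0772), when the median was -0.187, and the median was -0.608 without the third 48 h kidney. Hypoxia and glycolysis genes rose in 2 of 19 and fell in 1 at 6 h (2 and 1 adjusted over the list alone), with a median of 0.063 (adjusted p = 0.549). Adm, which encodes the vasodilator adrenomedullin, rose by 1.59 ± 0.18 and the glucose transporter Slc2a1 by 1.02 ± 0.22. At 48 h 2 of them were lower, the angiogenic factor Vegfa at -0.91 ± 0.11 and Egln1 at -0.71 ± 0.12. In the list of cell death and inflammasome genes 4 of 12 rose at 6 h and 2 fell (4 and 2 adjusted over the list alone), with a median of 0.043 (adjusted p = 0.468). Mlkl, the effector of necroptosis, rose by 1.49 ± 0.23 and Casp4 by 0.77 ± 0.14, whereas Bid fell by 0.70 ± 0.10 on the log2 scale. In the regeneration list 5 of 19 rose at 6 h and 1 fell (5 and 1 adjusted over the list alone), with a median of -0.055 and a mean of 0.42 (adjusted p = 0.241, and adjusted p = 0.00211 with fry, which called the list as higher). The growth factor gene Hbegf rose by 3.08 ± 0.25 and Lhx1 fell by 1.35 ± 0.22 on the log2 scale.

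From 48 h to 7 d, interferon response genes rose in 5 of 20 (11 adjusted over the list alone), with a median of 0.55 (adjusted p = 1.14e-05, and adjusted p = 0.507 with an estimated correlation), including B2m (0.63 ± 0.11, not called without the third kidneys of both times, adjusted p = 0.0664). Heat shock genes fell in 1 of 14, Cryab (-1.25 ± 0.16), and in 2 adjusted over the list alone, with a median of -0.19 (adjusted p = 0.0163, and adjusted p = 0.507 with an estimated correlation). The endothelium list passed with 0 of 14 genes called (limma, 6 at an unadjusted p under 0.05 and 0 adjusted over the list alone), at a median of 0.45 (adjusted p = 0.000851, and adjusted p = 0.69 with an estimated correlation), or 0.234 without the first 48 h kidney. Erythroid genes, with 0 of 5 called (limma, 4 at an unadjusted p under 0.05 and 3 adjusted over the list alone), had a median of -2.73 (adjusted p = 0.0141, and adjusted p = 0.54 with an estimated correlation, and 0.0629 without the first 7 d kidney, 0.129 with fry and 0.0597 without the third kidneys of both times). The second 7 d kidney stood apart, with means of the list minus sham of -2.2, 0.109 and -2.82 in the 3 kidneys at 7 d, while sham kidneys spanned -1.07 to 1.12. The median was -1.82 without the third 7 d kidney and -4.03 without the second. The lists that follow passed camera with the preset correlation at no time against sham, and fry called the adrenal list at 7 d (adjusted p = 0.036). At 6 h, 48 h and 7 d their medians were -0.004, -0.17 and -0.26 for podocytes, 0.018, -0.017 and 0.15 for T and NK cells, -0.0023, -0.058 and -0.074 for B and plasma cells, 0.094, 0.058 and 0.13 for perirenal fat and 0.064, -0.081 and -0.16 for the adrenal gland. They were -0.16, -0.085 and -0.18 for the respiratory chain and 0.18, 0.21 and 0.088 for common reference genes. Single members of these lists were called. At 6 h 1 fat gene and 1 reference gene were higher and 1 podocyte gene and 1 respiratory chain gene lower, at 48 h the reference gene Rplp0 was higher (0.90 ± 0.18), and at 7 d 1 T and NK cell gene was higher and 1 respiratory chain gene and 1 reference gene lower.

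Cyp2d9 and Cyp7b1, known for higher expression in male than in female mice, were among the largest decreases at 48 h. A loss of male-biased kidney gene expression was set against the fall of proximal tubule genes. Of the other 14 measured genes of a male-biased list 2 were called lower and 1 higher at 48 h against sham, with a median of -0.81, and the 29 proximal tubule genes outside that list had -0.69 (difference -0.122, two-sided permutation p = 0.493). This test leaves open whether male-biased genes fell beyond the other genes of the proximal tubule.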
